A study of Mus musculus with 18 samples.

How the data were processed

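The samples were intestinal stem cells of 8 to 16 week old mice, sorted by flow cytometry at 5000 to 10000 cells each, per the labels' protocols. Messenger RNA was captured on poly(A)-binding beads, amplified to cDNA with a SmartSeq kit and made into Nextera XT libraries, per the same protocols. The labels name no molecular identifiers, so the counts include amplified copies of molecules. Each library belonged to 1 of 4 groups, given by the genotype (wild type or Dlg1 conditional knock-out) and the time after tamoxifen injection (48 hours, called 2 days here, or 14 days). The labels do not say whether each replicate was a separate animal. The p-values measure only the spread between these samples, which may in part be technical.

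The values deposited by the authors were whole-number read counts per Ensembl gene, in 1 table per time and 1 column per library, with unequal column totals and no normalization. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.4.2a and the mouse genome build GRCm38 were used. The gene annotation, the counting program, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Values of near-identical copies, of overlapping genes and of antisense pairs are therefore uncertain, because their reads may have been split or counted on either strand. The column names begin with WT for wild type and, at 14 days, Dko for the knock-out. At 2 days the other columns begin with Dmin, which was read as Dlg1 minus, the knock-out, and every comparison that uses the 2 day libraries rests on this reading. The names carry no replicate number from the labels, so libraries were numbered within each group by their place in the table. These numbers pair nothing across groups.

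Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38. Of 43432 gene identifiers, 42462 matched a symbol and 40 shared a symbol with another identifier. Identifiers without a symbol held at most 0.218% of the counts of a library. Total counts ranged from 14.8 to 40.5 M per library at 2 days and from 11.1 to 15.7 M at 14 days. Each library was counted as 1 sample.

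Each time was tested alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood F-test compared knock-out with wild type. P-values were adjusted by Benjamini-Hochberg and called at an adjusted p under 0.05. Whether the genotype effect differed between times was tested in 1 fit of all 18 libraries with 4 group means. Each time was a separate table and may be a separate run or cohort, so a difference between times cannot be told apart from these. Only an additive difference between the tables cancels in this contrast. The genotype effect averaged over both times was tested in the same fit, a contrast added after seeing the data. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. CPM are counts scaled to a common library size by TMM-scaled totals, and log2 CPM used a prior count of 2. Totals are given in M (mega) counts. Exact permutation tests of single genes compared mean log2 CPM with a pseudocount of 0.5 and were two-sided.

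Gene lists for cell types, signalling pathways, cell cycle, stress, metabolism and possible contaminating cells, 30 in all, were fixed before the data were examined. So were the comparisons, the tests, the alternatives (those named as added apart) and the rule for the genes named. A list was tested where 3 or more members passed the filter, which left 29, since the haemoglobin and red cell list had fewer. The test was camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move one way on balance and does not set the list against other genes. For each list the mean log2 CPM of its members was also computed per library and compared by an exact two-sided permutation test.

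The genes named were Dlg1, Arhgap31 and Cdc42 in every comparison. Per time, they were also the 12 largest changes per direction among genes that passed, had an average log2 CPM of at least 3, had every knock-out library on the side of the fold change and were not predicted models. Where fewer than 5 passed in a direction, the genes of smallest p that met the other conditions filled the number to 5, and are said not to have passed. For the difference between times 5 per direction were taken without the condition on libraries. From each list described, up to 4 members of smallest p were named. An item that this rule would name is not reported here. Genes outside this rule are said to have been chosen after their values were seen.

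Alternatives were RLE size factors, upper-quartile factors, no filter on low counts, a minimum count of 50, DESeq2 1.42.0, limma voom with sample quality weights, all 18 libraries in 1 fit, the level of Y-linked transcripts as a covariate, and each library left out in turn. Added after seeing the data were a robust quasi-likelihood fit, a fit without the 2 libraries that stood apart, removal of satellite-like and mitochondrially encoded genes, and the letter before the number at the end of the column names at 14 days as a block. The gene and list tests were tested on simulated counts with 200 changed genes. At 2 days, with 12698, 12708 and 12737 genes tested, 16.5%, 73.3% and 94.3% of changed genes were recovered at 2-fold, 4-fold and 8-fold. At 14 days, with 13683, 13583 and 13555 genes tested, these shares were 31.3%, 86.3% and 98.9%. They rest on 200 independently simulated changes, which ease the Benjamini-Hochberg cut, so they may overstate recovery where few genes change. In the data Arhgap31 was not called at 14 days, at a log2 fold change of -2.55. A simulated shift of 1 log2 unit in the enterocyte list was called at both times, with 0 of 28 other lists called. Genes were simulated independently of each other, so this cannot show how often lists of correlated members are called falsely. The estimated correlation of the enterocyte list in the data was 0.541 at 2 days and 0.559 at 14 days. Figures were drawn with matplotlib 3.10.9.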

Results

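Gene expression was measured in 18 libraries of sorted mouse intestinal stem cells, the dividing cells at the base of the crypts. There were 4 wild-type and 4 Dlg1 knock-out libraries at 2 days after tamoxifen, the drug that induces the deletion, and 5 of each genotype at 14 days. Libraries at 2 days held 14.8 to 40.5 M counts on 16073 to 18750 genes, and those at 14 days held 11.1 to 15.7 M counts on 20398 to 26773 genes. Mitochondrially encoded genes took 26.1% to 49.1% of counts at 2 days and 6.21% to 26.3% at 14 days. At 14 days the knock-out libraries were shallower, at 11.9 ± 0.947 against 14.1 ± 1.11 M counts (SD, n = 5 each, two-sided exact permutation p = 0.0159). A pair of libraries stood apart from the rest of their tables. Wild-type library 1 at 2 days had the highest total and the highest mitochondrial share, and knock-out library 5 at 14 days had 47.0% of its counts in satellite-like gene models, against 0.0552% to 10.1% in the other libraries of that time.

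The series asks how loss of Dlg1, a scaffold protein of the apical-basal polarity machinery, bears on Arhgap31, a GTPase-activating protein for Cdc42 and Rac1, on the small GTPase Cdc42 and on the response to Wnt. Dlg1 itself (ENSMUSG00000022770, chromosome 16, 31663443 to 31875129, plus strand, GRCm38) stood at 48.3, 63.5, 56.3 and 69.5 CPM in wild-type libraries 1 to 4 at 2 days, and at 43.3, 58.0, 38.4 and 43.1 CPM in knock-out libraries 1 to 4. The means were 59.4 ± 9.18 and 45.7 ± 8.49 CPM (SD, n = 4 each), a log2 fold change of -0.38 with a standard error of 0.19. At this time 3 of 4 knock-out libraries lay below every wild-type library, and the difference missed the threshold of the exact test (two-sided exact permutation p = 0.0857). At 14 days the wild-type libraries 1 to 5 held 64.1, 65.5, 60.5, 85.8 and 84.1 CPM of Dlg1, and the knock-out libraries 64.0, 44.7, 41.8, 70.3 and 101 CPM. The means of 72.0 ± 11.95 and 64.3 ± 23.8 CPM differed by less than their spread (SD, n = 5 each, two-sided exact permutation p = 0.389), with a log2 fold change of -0.17 and a standard error of 0.22. It was -0.40 without knock-out library 5 and -0.06 without knock-out library 3. The adjusted p of Dlg1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.866 at 2 days and 0.957 at 14 days. These counts cover the whole gene, including exons outside the deleted part, so they do not fully check the deletion or the labels.

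Arhgap31 was lower in every knock-out library than in any wild-type library at both times. At 2 days Arhgap31 (ENSMUSG00000022799, chromosome 16, 38598340 to 38713274, minus strand) held 0.453 ± 0.275 CPM in knock-out and 3.24 ± 1.86 CPM in wild-type libraries (SD, n = 4 each), from 4 to 15 and 31 to 164 raw counts. The fitted level was 14.0% of wild type, a log2 fold change of -2.84 with a standard error of 0.69. At 14 days it held 1.71 ± 0.828 against 10.1 ± 2.78 CPM (SD, n = 5 each), from 7 to 35 and 118 to 222 raw counts. The fitted level was then 17.1% of wild type, a log2 fold change of -2.55 with a standard error of 0.38. Two-sided exact permutation tests gave p = 0.0286 at 2 days and p = 0.00794 at 14 days, the smallest values that 70 and 252 assignments allow. Within each time alone Arhgap31 missed the threshold of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.866 at 2 days and 0.145 at 14 days). DESeq2 called it at both times. Averaged over both times, a contrast added after the data were seen, Arhgap31 fell by 2.71 on the log2 scale with a standard error of 0.36. It was the single gene called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00328). In 6 of 100 splits of the libraries within each time, the real one included, the smallest adjusted p was as small. The call of Arhgap31 held under all 11 alternatives, with adjusted p from 1.71e-11 to 0.0251, and in each of the 18 fits that left out a library. In those fits a second gene passed without wild-type library 3 (Aim2), knock-out library 1 (Gsdmc2) or knock-out library 4 (Aim2) at 2 days, and without wild-type library 3 (Cox7a1) or knock-out library 5 (Dclre1c) at 14 days. The effect did not differ detectably between times, with a difference of 0.28 on the log2 scale and a standard error of 0.67 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.967).

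**Figure D1:**
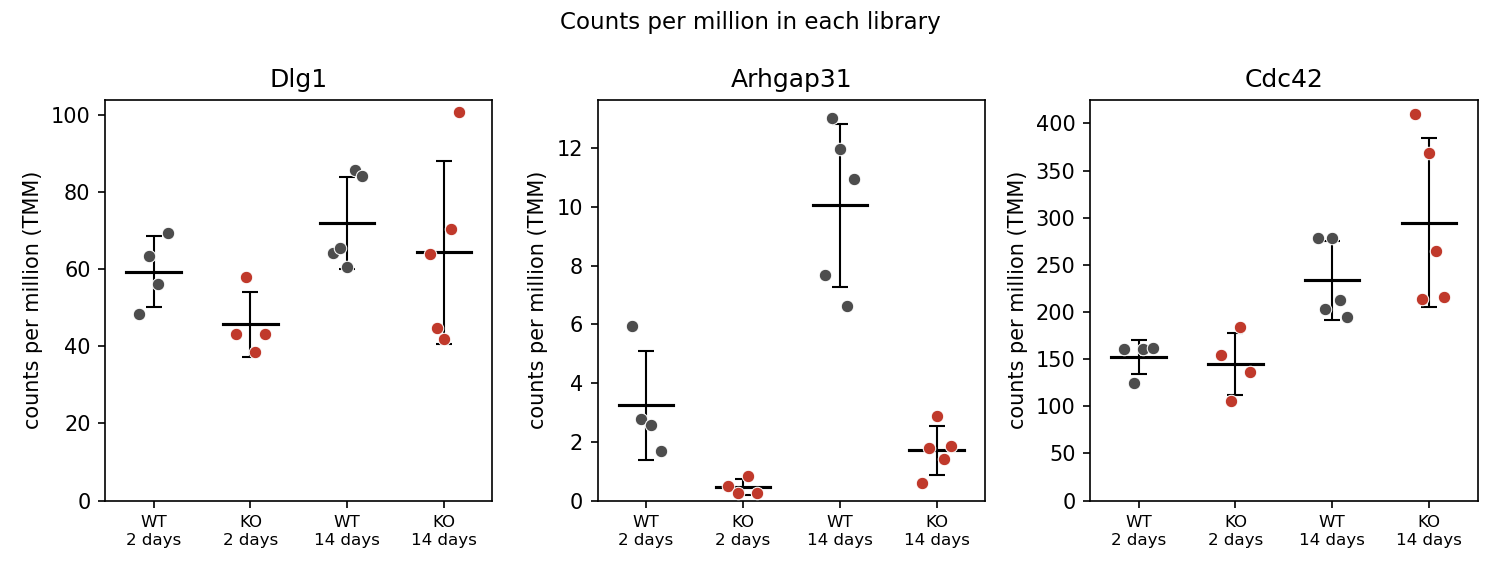
CPM (vertical axis, TMM-scaled) of Dlg1, Arhgap31 and Cdc42 in each library of the 4 groups (WT, wild type; KO, Dlg1 knock-out; 2 and 14 days after tamoxifen), with points for libraries, horizontal bars for means and whiskers for SD (n = 4, 4, 5 and 5). Arhgap31 lies lower in every knock-out library than in any wild-type library of the same time, at means of 0.453 against 3.24 CPM at 2 days and 1.71 against 10.1 CPM at 14 days, while the groups overlap for Dlg1 and Cdc42.

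Cdc42 (ENSMUSG00000006699, chromosome 4, 137319696 to 137357720, minus strand) held 145 ± 33.2 CPM in knock-out and 152 ± 17.9 CPM in wild-type libraries at 2 days (SD, n = 4 each, two-sided exact permutation p = 0.629). At 14 days it held 295 ± 89.8 and 234 ± 41.5 CPM, a log2 fold change of 0.34 with a standard error of 0.21 that did not pass (SD, n = 5 each, two-sided exact permutation p = 0.183). The fixed list of regulators and effectors of Cdc42 was not called at either time, with adjusted p of 0.209 and 0.760 by camera with Benjamini-Hochberg adjustment. Of its 52 tested members at 2 days, 21 had a positive and 31 a negative fold change, and none passed adjusted over the list alone or over all genes. Cdc42ep5 and Baiap2, both effectors of Cdc42, had log2 fold changes of 0.88 ± 0.35 and 1.05 ± 0.44 (SE), and Arhgap1, another GTPase-activating protein for Cdc42, had -0.33 ± 0.15 (SE). At 14 days 1 of 53 members passed adjusted over the list alone, which was Arhgap31 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the list, adjusted p = 5.50e-04), and none passed over all genes. Rhoa had a log2 fold change of 0.30 ± 0.15 (SE) and Cdc42bpb, a kinase that binds Cdc42, 0.36 ± 0.18 (SE).

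Arhgap31 lies on the same chromosome as Dlg1. Of 132 other tested genes within 10 Mb of Dlg1, 13 had an unadjusted p under 0.05 for the averaged effect, 6 of them lower in the knock-out. This share of 9.85% narrowly exceeded the 9.09% that marks the 95th percentile of 12417 windows of as many genes elsewhere, whose median was 5.30%. The 13 genes include Sst, averaged at -1.78 although its log2 fold change at 14 days was positive, so its effect was not constant. These windows were moved along gene by gene, so they overlapped widely and were not independent. Hspbap1, chosen after its values were seen, lies between Dlg1 and Arhgap31 (chromosome 16, 35770375 to 35828477, plus strand, with an antisense gene over its exons). Hspbap1 held 2.48 ± 0.936 against 5.94 ± 0.373 CPM at 2 days (SD, n = 4 each) and 11.5 ± 0.83 against 16.1 ± 3.15 CPM at 14 days (SD, n = 5 each). Its averaged log2 fold change was -0.87 with a standard error of 0.18, and it was not called (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.408), while DESeq2 called it (adjusted p = 0.00200).

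**Figure D2:**
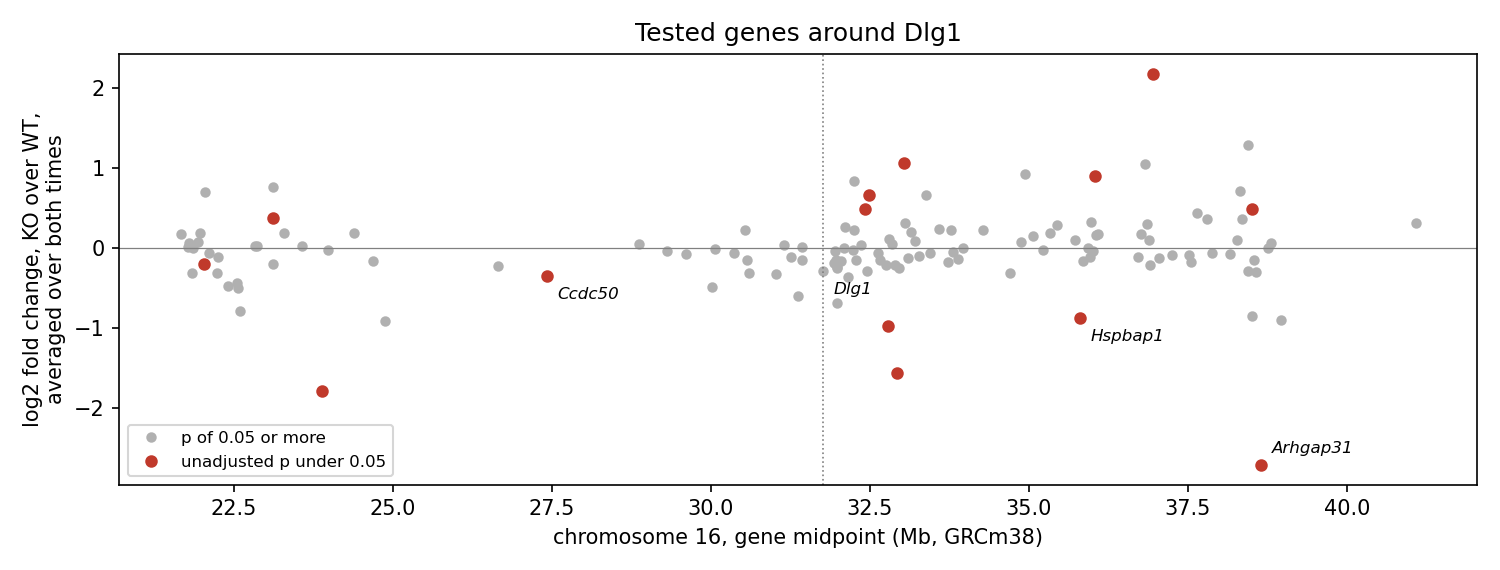
Log2 fold change of knock-out over wild type, averaged over both times (vertical axis), against the midpoint of each tested gene on chromosome 16 within 10 Mb of Dlg1 (horizontal axis, Mb, GRCm38), with red points for an unadjusted p under 0.05 and the dotted line at Dlg1. Arhgap31 has the lowest value, at -2.71, and 13 of the 132 other genes are red, 6 of them below 0.

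At 2 days, the largest positive values among the genes named by the rule for single genes were those of the gasdermin C family, which form membrane pores. Gsdmc2 held 36.1 ± 31.1 CPM in knock-out and 1.37 ± 0.925 CPM in wild-type libraries (SD, n = 4 each), a log2 fold change of 4.71 ± 0.78 (SE), and Gsdmc4 had 3.63 ± 0.77 (SE). Reads shared between these neighbouring copies may have been split, so single values are uncertain. St3gal4, a sialyltransferase, had 1.65 ± 0.32 (SE), the alcohol dehydrogenase family gene Adh6a 1.83 ± 0.36 (SE), and Car4, a membrane carbonic anhydrase, 2.08 ± 0.43 (SE). In the other direction Aim2, a sensor of cytosolic DNA, had a log2 fold change of -4.63 ± 0.81 (SE), and Itgam, an integrin of myeloid cells with another annotated gene over its exons, had -2.07 ± 0.61 (SE), or -0.87 without wild-type library 1. Ralgps2, Ccdc50 and Rbak had log2 fold changes of -0.59, -0.53 and -0.67. None of these genes passed, with adjusted p of 0.323 for Gsdmc2 and Aim2 and up to 0.866 for the others by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the level of Y-linked transcripts as a covariate Gsdmc4 and, at 4.40, Gsdmc2 were called. By the same test Gsdmc2 then had an adjusted p of 0.0130, against 2.57e-04 to 0.513 over its 11 alternatives with edgeR, DESeq2 or limma voom and Benjamini-Hochberg adjustment, 4 of them under 0.05.

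Over all 13031 genes tested at 2 days, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0. At an unadjusted p under 0.05 there were 640 genes, 355 higher and 285 lower in the knock-out, against 651.55 expected by chance. The smallest adjusted p was 0.317, for Cox7a1, a subunit of cytochrome c oxidase chosen after its values were seen, with a log2 fold change of 2.82 ± 0.43 (SE). DESeq2 called 13 genes, and limma voom 0. Those higher by DESeq2 were Gsdmc2, Gsdmc4, Cox7a1, St3gal4, Adh6a, Car4, Clca1, Ces1f, Pla2g4c and Cyp4f40, and those lower were Arhgap31, Aim2 and Zfp354c. Aim2 held 60.0 to 77.7 CPM in wild-type libraries 1, 2 and 4 but 3.74 CPM in wild-type library 3, within the range of 0.835 to 4.42 CPM of the knock-out libraries. Without wild-type library 3 Aim2 was called (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0103, against 8.17e-04 to 0.575 over its 11 alternatives).

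At 2 days camera with a preset correlation called 5 lists, led by higher markers of absorptive enterocytes in the knock-out libraries. All 5 calls were lost by camera with Benjamini-Hochberg adjustment when the correlation was estimated (adjusted p = 0.862 with an estimated correlation), and 2 of 4 knock-out libraries lay near the wild-type mean in enterocyte markers, at 0.0841 and -0.0867. Of 37 tested enterocyte markers 36 had a positive fold change, with a median log2 fold change of 1.16, and 14 were higher at an unadjusted p under 0.05. Rbp2, which carries retinol, had 1.59 ± 0.50 (SE), Mttp, which loads lipid onto lipoproteins, 0.95 ± 0.30 (SE), the fatty acid binding protein Fabp1 1.62 ± 0.53 (SE) and the fructose transporter Slc2a5 1.34 ± 0.46 (SE). Markers of tuft cells, the chemosensory cells of the epithelium, had a median of 1.01 with 13 of 16 members positive, among them Alox5ap at 2.31 ± 0.78 (SE), Spib at 1.503 ± 0.69 (SE) and Fyb at 1.49 ± 0.74 (SE), while Cd24a had -0.61 ± 0.25 (SE). Genes of fatty acid oxidation and PPAR targets had a median of 0.24 with 22 of 28 positive, 7 of them at an unadjusted p under 0.05, including Slc25a20, Angptl4 and Eci2 at 0.52, 1.42 and 0.40, and Fabp1 again. Markers of Paneth cells, which secrete antimicrobial peptides, had a median of 0.15 with 12 of 19 positive, led by Guca2b at 1.02 ± 0.42 (SE), and with Ang4 at 0.78, Habp2 at 0.54 and Defa24 at 0.35. Without knock-out library 1 Rbp2, Mttp, Fabp1, Slc2a5 and Guca2b had 0.88, 0.51, 0.77, 0.83 and 0.43. Without knock-out library 3 Ang4 had 0.38, and without wild-type library 1 Cd24a had -0.25 and Nusap1 -0.37. Habp2 turned without knock-out library 2 (-0.14) and Defa24 without wild-type library 4 (-0.02). Genes of G2/M and mitosis, called lower only with the preset correlation (adjusted p = 0.862 with an estimated correlation, by camera with Benjamini-Hochberg adjustment), had a median of -0.18 and 28 of 35 members negative, 8 of them at an unadjusted p under 0.05, including Nusap1 at -0.60 ± 0.21 (SE), Hmmr at -0.54 ± 0.20 (SE), Kif11 at -0.41 and Anln at -0.39. No member of these 5 lists passed adjusted over the list alone or over all genes.

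These 5 of 29 lists were called at 2 days by camera with Benjamini-Hochberg adjustment, with adjusted p of 1.79e-06 for enterocyte, 9.06e-04 for G2/M, 0.00179 for fatty acid oxidation and 0.0487 for Paneth and tuft markers. None was called with an estimated correlation (adjusted p = 0.862), and fry called none (smallest adjusted p = 0.851). Over 11 alternatives the adjusted p ranged up to 0.862, from 3.69e-15 for enterocyte, 1.50e-07 for G2/M, 5.53e-10 for fatty acid oxidation, 0.00697 for Paneth and 9.52e-04 for tuft markers. All 4 knock-out libraries lay below the wild-type mean for G2/M and above it for fatty acid oxidation and Paneth markers, and 3 of 4 lay above it for enterocyte and tuft markers. The list means per library missed the threshold of the exact test, with two-sided exact permutation p of 0.257 for enterocyte, 0.200 for tuft and G2/M, 0.0571 for fatty acid oxidation and 0.571 for Paneth markers. The enterocyte mean ranged from -0.0867 to 2.16 log2 units above the wild-type mean in knock-out libraries, and without knock-out library 1 its median was 0.21 and its adjusted p 0.0733. Without wild-type library 4 the G2/M and fatty acid oxidation calls ended (medians -0.10 and 0.21, adjusted p = 0.190 and 0.217). The G2/M median was -0.09 without knock-out library 2 and -0.26 without knock-out library 3. The tuft call ended without knock-out library 2 (0.27, adjusted p = 0.811) and without wild-type library 3 (0.91, adjusted p = 0.188). The Paneth call ended without knock-out library 2 (-0.08), knock-out library 3 (-0.07) and wild-type library 2 (0.11), and turned without wild-type library 4 (-0.20). Its median moved to 0.05 and 0.96 without wild-type libraries 1 and 3 and to 0.32 and 0.29 without knock-out libraries 1 and 4. Upper-quartile scaling, the covariate of Y-linked transcripts, and for single lists a minimum count of 50, no filter or the joint fit of all libraries also ended the Paneth or tuft calls.

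Stem cell markers and Wnt target genes did not differ detectably between genotypes at 2 days. The 26 stem cell markers had a median log2 fold change of -0.08, with 16 negative, and Lgr5, the Wnt-responsive receptor that marks these cells, had -0.40 ± 0.23 (SE), Tnfrsf19 -0.35 ± 0.22 (SE), Aqp4 -0.31 ± 0.20 (SE) and Slc12a2 -0.27 ± 0.17 (SE). The 21 tested Wnt target genes had a median of -0.10, with Nkd2 at 1.92 ± 0.77 (SE) and Prox1 at -0.83 ± 0.36 (SE). Components of the Wnt pathway had a median of -0.06 over 39 members, among them Apc at -0.38 ± 0.17 (SE) and Dvl3 at -0.44 ± 0.21 (SE). The adjusted p by camera with Benjamini-Hochberg adjustment was 0.171, 0.312 and 0.402 for these 3 lists. The means of the stem cell and Wnt target lists per library gave two-sided exact permutation p of 0.371 and 1. Polarity complexes, with 19 of 31 members positive, Mpp6 at -0.49 ± 0.19 (SE) and Mpp2 at 2.37 ± 1.07 (SE), had an adjusted p of 0.831, and tight and adherens junctions one of 0.954, by the same test. No member of these 5 lists passed adjusted over the list alone.

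Among secretory and other cell types at 2 days, goblet markers had a median of 0.34 with 16 of 21 positive (camera with Benjamini-Hochberg adjustment, adjusted p = 0.171). Clca1, a secreted goblet cell protein, passed adjusted over the list alone (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the list, adjusted p = 0.0272) at 1.66 ± 0.40 (SE). Tff3 and Agr2 had 0.86 ± 0.30 (SE) and 0.63 ± 0.30 (SE), and Sytl2 had -0.81 ± 0.36 (SE). Enteroendocrine markers (0.402), immune markers (0.695) and stromal, endothelial and neural markers (0.209) were not called, these being adjusted p by camera with Benjamini-Hochberg adjustment. Itgam passed adjusted over the immune list alone (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the list, adjusted p = 0.0402), with 55.6 CPM in wild-type library 1 and 8.00 to 10.1 CPM in the other wild-type libraries. The remaining lists were not called either, with adjusted p by camera with Benjamini-Hochberg adjustment of 0.402 for S phase, BMP and p53, 0.171 for fetal-like and Yap targets and for interferon and MHC class I, 0.980 for Notch, 0.444 for EGF and MAPK, 0.631 for the unfolded protein response and 0.438 for cholesterol synthesis. By the same test the adjusted p was 0.344 for MHC class II, 0.695 for extracellular matrix, 0.168 for dissociation stress, 0.915 for mitochondrially encoded genes and 0.954 for sex-linked transcripts. Library means of the sex-linked list split each genotype. Relative to the wild-type mean, they were 2.14 to 2.52 in wild-type libraries 3 and 4 and knock-out libraries 1 and 2. In the other libraries they were -2.49 to -2.09, so each group may hold both sexes. At 14 days this list split each group likewise, and the main fits did not model it. Dissociation stress was called in 4 of 8 fits that each left out a library, with adjusted p from 0.00554 to 0.811 by camera with Benjamini-Hochberg adjustment. Median, mean and test differed in sign for the enteroendocrine, Notch, BMP and unfolded protein response lists.

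**Figure D3:**
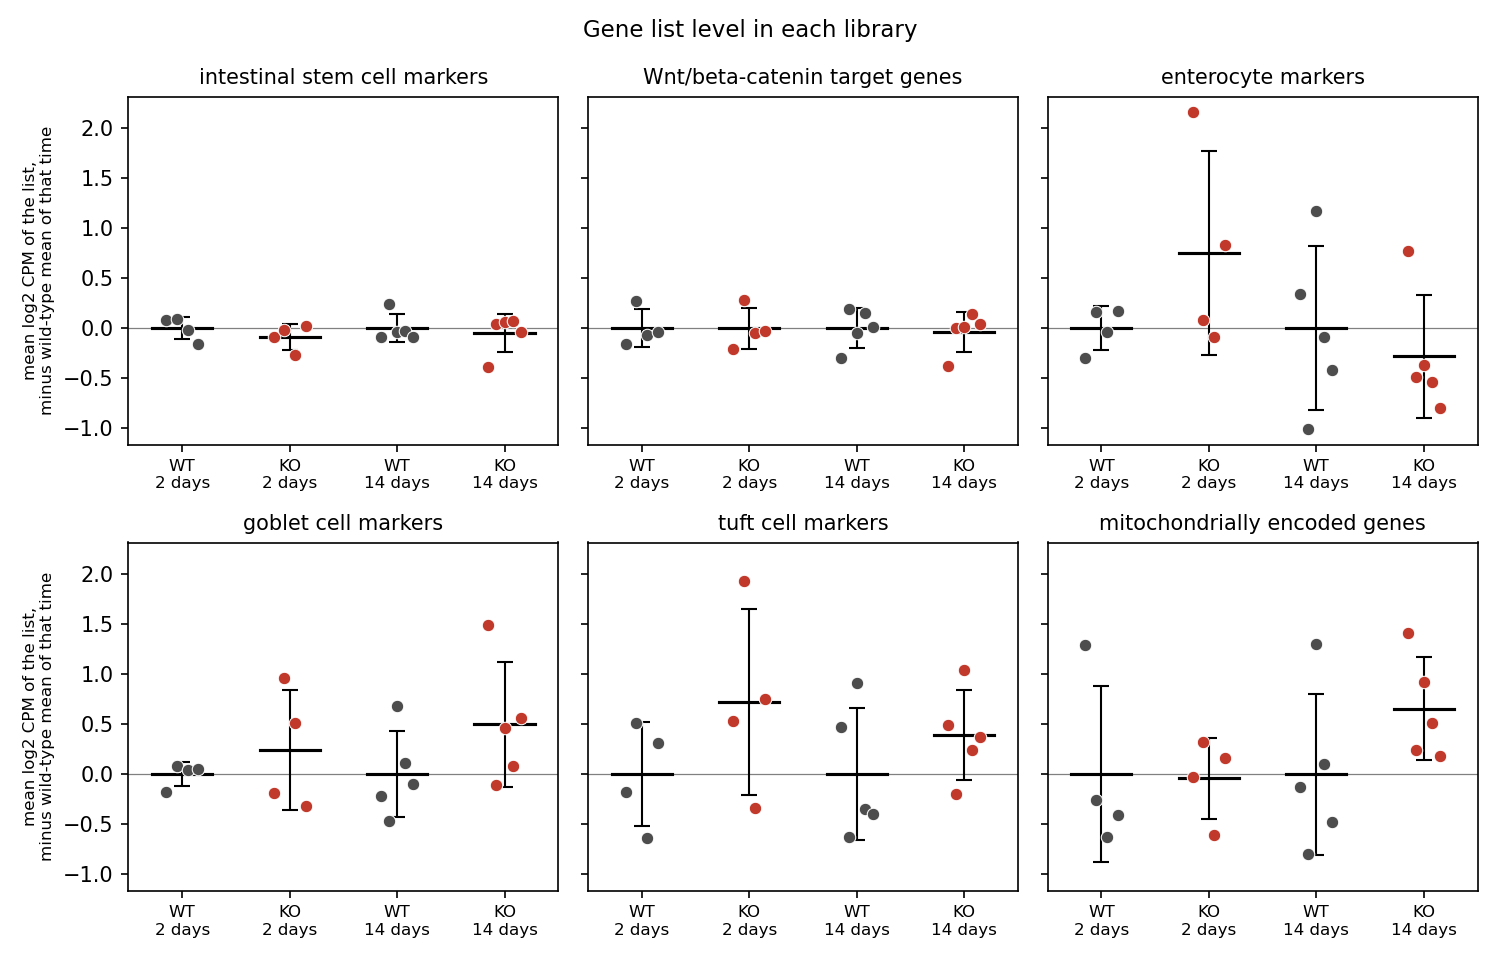
Mean log2 CPM of the members of 6 gene lists in each library, minus the wild-type mean of the same time (vertical axis, log2 units), by group (WT, wild type; KO, Dlg1 knock-out), with points for libraries, horizontal bars for means and whiskers for SD (n = 4, 4, 5 and 5). The groups overlap in every panel, and the knock-out libraries spread from -0.0867 to 2.16 in enterocyte markers at 2 days.

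After 14 days, as at 2 days, no single gene passed the test over all genes. B2m, the light chain of MHC class I, had a log2 fold change of 1.04 ± 0.27 (SE) in knock-out over wild type, Abhd5, a coactivator of triglyceride breakdown, 0.74 ± 0.19 (SE), the mitochondrial ribosomal gene Mrpl40 0.73 ± 0.19 (SE), Cbr4 0.67 ± 0.17 (SE) and Pttg1, the securin of mitosis, 0.51 ± 0.14 (SE). Eepd1 had -0.96 ± 0.26 (SE), the phospholipase Plcd1 -0.89 ± 0.27 (SE), the zinc finger gene Zfp263 -0.54 ± 0.14 (SE), Phf13 -0.50 ± 0.16 (SE) and Vmp1, a membrane protein of autophagy, -0.43 ± 0.14 (SE). These 10 genes did not pass, all with an adjusted p of 0.957 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test called 0 of 13991 genes, with 558 at an unadjusted p under 0.05, 341 higher and 217 lower, against 699.55 expected by chance. DESeq2 called 1 gene, Arhgap31, and limma voom 0.

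At 14 days camera with a preset correlation called 6 lists, among them higher goblet, enteroendocrine and tuft markers in the knock-out libraries. All 6 calls were lost by camera with Benjamini-Hochberg adjustment when the correlation was estimated (adjusted p = 0.899 with an estimated correlation). Goblet markers had a median log2 fold change of 0.50 with 21 of 23 members positive, including Atoh1, the transcription factor that commits cells to the secretory fate, at 0.79 ± 0.26 (SE), Agr2 at 1.09 ± 0.42 (SE), Ramp1 at 1.05 ± 0.45 (SE) and Zg16 at 1.72 ± 0.85 (SE). Enteroendocrine markers had a median of 0.36 with 22 of 23 positive, including the hormone genes Ghrl at 2.34 ± 0.70 (SE), Sst at 1.59 ± 0.49 (SE) and Gip at 1.13 ± 0.69 (SE), and Insm1 at 0.84 ± 0.37 (SE). Tuft markers had a median of 0.39 with 17 of 20 positive, including Rgs13 at 1.20 ± 0.60 (SE), Alox5ap at 0.95 ± 0.46 (SE) and Avil at 0.49 ± 0.30 (SE), with Gfi1b at -1.33 ± 0.76 (SE). Enterocyte markers, called lower only with the preset correlation (adjusted p = 0.899 with an estimated correlation, by camera with Benjamini-Hochberg adjustment), had a median of -0.35 and 30 of 37 negative, including the brush border enzymes Lct at -1.45 ± 0.56 (SE), Treh at -1.02 ± 0.46 (SE) and Alpi at -0.76 ± 0.33 (SE), while Ada had 0.64 ± 0.23 (SE). The EGF and MAPK list had a median of -0.14 and 23 of 29 negative, including its feedback genes Etv5, Dusp6, Spry2 and Errfi1 at -0.78, -0.48, -0.37 and -0.29. Mitochondrially encoded genes had a median of 0.61 and 9 of 10 positive, including mt-Cytb at 0.83 ± 0.46 (SE), mt-Co1 at 0.70, mt-Nd4 at 0.64 and mt-Nd2 at 0.62. Without knock-out library 1 Zg16, Ramp1 and Agr2 had 0.21, 0.47 and 0.45, mt-Cytb and mt-Co1 had 0.40 and 0.31, and Gip turned to -0.17. Without wild-type library 3 Gfi1b, Dusp6 and Spry2 had -0.57, -0.19 and -0.11. No member of these 6 lists passed adjusted over the list alone or over all genes. The mitochondrial share of all counts was 15.9% ± 6.28 in knock-out and 12.3% ± 8.07 in wild-type libraries (SD, n = 5 each, two-sided exact permutation p = 0.452).

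Camera with Benjamini-Hochberg adjustment called these 6 of 29 lists, with adjusted p of 1.69e-04 for goblet, 2.56e-04 for mitochondrially encoded, 0.00378 for enterocyte, 0.00411 for enteroendocrine, 0.00608 for tuft and 0.0199 for EGF and MAPK genes. None was called with an estimated correlation (adjusted p = 0.899), and fry called none (smallest adjusted p = 0.902). Over the alternatives the adjusted p ranged up to 0.902, from 1.07e-04 for goblet, 1.01e-06 for mitochondrially encoded, 4.18e-04 for enterocyte, 0.00329 for enteroendocrine, 6.33e-05 for tuft and 0.00289 for EGF and MAPK genes. Of 5 knock-out libraries, 5 lay above the wild-type mean for mitochondrially encoded genes, 4 above it for goblet, enteroendocrine and tuft markers, and 4 below it for the enterocyte and the EGF and MAPK lists. The list means per library missed the threshold of the exact test, with two-sided exact permutation p of 0.206 for goblet, 0.167 for mitochondrially encoded, 0.571 for enterocyte, 0.127 for enteroendocrine, 0.278 for tuft and 0.222 for EGF and MAPK genes. The goblet and mitochondrial calls held in all 10 fits that left out a library, although without knock-out library 1 the medians were 0.16 and 0.36, and the mitochondrial median was 1.09 without wild-type library 3. The enterocyte call ended without wild-type library 3 (median -0.10, adjusted p = 0.701), without knock-out library 5 (-0.26, adjusted p = 0.166) and with limma voom (-0.23, adjusted p = 0.0671), and its median was -0.79 without knock-out library 1. The enteroendocrine call ended without knock-out library 1 (0.14, adjusted p = 0.214) and wild-type library 4 (0.22, adjusted p = 0.0967). The tuft call ended without wild-type library 2 (0.27, adjusted p = 0.185), wild-type library 4 (0.30, adjusted p = 0.0512) and knock-out library 3 (0.17, adjusted p = 0.121). Without wild-type library 3 the enteroendocrine and tuft medians were 0.61 and 0.82. The EGF and MAPK call ended without wild-type library 2 (-0.06), 3 (-0.13) or 4 (-0.13), without knock-out library 1 (-0.11) and with limma voom (-0.13, adjusted p = 0.0505).

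The stem cell and Wnt lists were not called at 14 days. Stem cell markers had a median of -0.07 with 16 of 26 negative (camera with Benjamini-Hochberg adjustment, adjusted p = 0.435), and among them Slc14a1 had -0.72 ± 0.38 (SE) and Smoc2 -0.22 ± 0.18 (SE). Wnt target genes had a median of -0.04 (adjusted p = 0.496 by the same test), with Myc at -0.52 ± 0.22 (SE), Sp5 at -0.39 ± 0.29 (SE) and Cd44 at -0.20 ± 0.18 (SE). Components of the Wnt pathway had 31 of 39 members negative, with a median of -0.10, and missed the threshold (adjusted p = 0.0577 by the same test). Among them the receptors Fzd5 and Fzd4 had -0.54 ± 0.21 (SE) and -1.33 ± 0.58 (SE), Axin1 had -0.34 ± 0.17 (SE), and Wnt3 had 0.74 ± 0.39 (SE). The 9 tested members of MHC class II were all positive, with a median of 0.30, and had the same adjusted p of 0.0577. In 10 fits that each left out a library, Wnt components were called in 2 (adjusted p from 0.00673 to 0.214 by camera with Benjamini-Hochberg adjustment) and MHC class II in 5 (0.00126 to 0.846). By the same test Paneth markers were called in 2 of these fits (6.16e-10 to 0.949). Two-sided exact permutation tests of the list means gave p = 0.627 for stem cell markers, 0.690 for Wnt targets and 0.183 for Wnt components.

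For the other lists at 14 days the adjusted p by camera with Benjamini-Hochberg adjustment was 0.435 for polarity complexes and extracellular matrix, 0.316 for junctions, 0.168 for Paneth markers, 0.151 for immune markers, 0.779 for stromal, endothelial and neural markers, 0.368 for S phase and dissociation stress, and 0.536 for G2/M. By the same test it was 0.995 for fetal-like and Yap targets, 0.760 for Notch, 0.356 for BMP, 0.496 for p53, 0.601 for the unfolded protein response and for interferon and MHC class I, 0.714 for cholesterol synthesis, 0.454 for fatty acid oxidation and 0.914 for sex-linked transcripts. Of the 6 immune markers tested, all had positive fold changes, such as Lck at 0.52 ± 0.41 (SE) and Cd79b at 0.56 ± 0.49 (SE). Among dissociation stress genes, the near-identical heat shock genes Hspa1b and Hspa1a had -0.95 ± 0.33 (SE) and -0.83 ± 0.34 (SE). In the S phase list Gins2 and Pola1 had 0.52 ± 0.24 (SE) and 0.33 ± 0.14 (SE). Median, mean and test differed in sign for the Paneth, cholesterol synthesis and sex-linked lists.

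The genotype effect on enterocyte markers differed between the times by camera with a preset correlation, and this was lost when the correlation was estimated (camera with Benjamini-Hochberg adjustment, adjusted p = 0.900 with an estimated correlation). The change from 2 to 14 days had a median of -1.73 on the log2 scale with 35 of 37 members negative, among them Lct at -3.40 ± 1.14 (SE), Alpi at -2.22 ± 0.66 (SE), Slc2a5 at -2.08 ± 0.64 (SE) and Mttp at -1.22 ± 0.38 (SE). Of these members 3 passed adjusted over the list alone and 0 over all genes. The change was also negative for fatty acid oxidation (median -0.28, 22 of 28 negative, with Angptl4 at -1.67), for dissociation stress (-0.22, 22 of 30, with Hspa1b at -2.71 and Hspa1a at -2.63) and for EGF and MAPK genes (-0.20, 21 of 29, with Spry2 at -1.28, Dusp5 at -0.91 and Map2k2 at -0.87). It was positive for G2/M (0.22, 29 of 35 positive, with Hmgb2 at 1.40 and Hmmr at 0.71) and for mitochondrially encoded genes (0.92, 9 of 10 positive, with mt-Nd2 at 1.37). Without knock-out library 1 at 2 days Lct, Alpi, Slc2a5 and Mttp had -1.81, -1.32, -1.57 and -0.78. Without wild-type library 1 at 2 days mt-Nd2 and Hmgb2 had 0.20 and 0.61, and without knock-out library 2 at 2 days Hspa1a had -1.29. The adjusted p by camera with Benjamini-Hochberg adjustment was 4.95e-07 for enterocyte, 0.00178 for G2/M, 0.00662 for fatty acid oxidation, 0.0125 for mitochondrially encoded, 0.0365 for dissociation stress and 0.0384 for EGF and MAPK genes. Each of these 6 calls was lost when the correlation was estimated (adjusted p = 0.900 with an estimated correlation), and fry called none (smallest adjusted p = 0.832). This test of lists was added after the data had been examined. Time cannot be told apart from a run or cohort of each table, so these differences need not come from time. The enterocyte call held in all 18 fits that left out a library, with medians from -1.99 to -0.62, the latter without knock-out library 1 at 2 days, and of -0.91 without wild-type library 3 at 14 days.

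The other 5 of these calls each ended without at least 1 library. Over their alternatives the adjusted p ranged up to 0.900, from 2.09e-10 for enterocyte, 1.15e-07 for G2/M, 5.66e-07 for fatty acid oxidation, 0.00950 for mitochondrially encoded, 1.57e-04 for dissociation stress and 0.00766 for EGF and MAPK genes. Without wild-type library 4 at 2 days the G2/M and fatty acid oxidation calls ended (medians 0.19 and -0.23, both with an adjusted p of 0.0858 by camera with Benjamini-Hochberg adjustment). The G2/M median was 0.37 without wild-type library 2 at 2 days and 0.34 without knock-out library 5 at 14 days. Without wild-type library 2 at 2 days the dissociation stress and EGF and MAPK medians were -0.36 and -0.31. The call on mitochondrially encoded genes ended without wild-type library 1 at 2 days (0.17), knock-out library 3 at 2 days (0.82), wild-type library 2 at 14 days (0.78) and knock-out library 1 at 14 days (0.64). The dissociation stress call ended without wild-type libraries 3 (-0.22) and 4 (-0.13) or knock-out library 2 (-0.18) at 2 days, and without wild-type libraries 2 (-0.14) and 3 (-0.23) or knock-out libraries 1 (-0.23), 2 (-0.21), 4 (-0.24) and 5 (-0.19) at 14 days. The EGF and MAPK call ended without wild-type libraries 1 (-0.15) and 4 (-0.14) or knock-out libraries 1 (-0.15), 2 (-0.19) and 4 (-0.16) at 2 days, and without wild-type libraries 2 (-0.06) and 4 (-0.10) or knock-out libraries 1 (-0.08), 3 (-0.14) and 5 (-0.21) at 14 days. The other 23 lists were not called, with adjusted p of 0.0691 or above. Enteroendocrine markers were closest (median 0.40) and were called in 7 of 18 fits that each left out a library (adjusted p from 9.44e-04 to 0.524 by camera with Benjamini-Hochberg adjustment). Sst passed adjusted over that list alone at 6.70 ± 1.57 (SE), as did Itgam over the immune list. The averaged log2 fold change of Sst was -1.78, so this difference came mostly from lower Sst in the knock-out libraries at 2 days. Median, mean and test differed in sign for Wnt targets, BMP and the unfolded protein response.

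Among the genes named by the rule for single genes, the difference of effects between times was -4.97 ± 0.91 (SE) for Gsdmc2 and 4.19 ± 0.88 (SE) for Aim2. Ces1f, Adh6a, Cyp4f40 and Hkdc1 had -3.25, -2.11, -2.002 and -1.60, and Itgam, Rab32, Rida and Mad2l1, a gene of the spindle checkpoint, had 2.34, 1.48, 1.23 and 0.89. Without wild-type library 1 at 2 days Itgam had 1.16. None of these passed, with adjusted p from 0.289 for Gsdmc2 to 0.762 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test called 0 of 15458 genes, with 921 at an unadjusted p under 0.05, 359 higher and 562 lower, against 772.9 expected by chance. DESeq2 called 13 genes, among them Gsdmc2, Aim2, Adh6a, Cyp4f40 and Hkdc1, and limma voom 0. Gsdmc2 was called without knock-out library 1 at 2 days (-5.34) and Aim2 without wild-type library 3 at 2 days (4.58). Gsdmc2 was also called with the covariate of Y-linked transcripts (-4.51, adjusted p = 0.0427 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Over its 11 alternatives with edgeR, DESeq2 or limma voom the adjusted p ranged from 3.40e-17, without a filter on low counts, to 0.642 with Benjamini-Hochberg adjustment.

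Across the 12480 genes tested at both times, the genotype effects at 2 and 14 days were close to uncorrelated, with Pearson's r of -0.042 and Spearman's rho of -0.020, computed across genes, which are not independent replicates. No gene was called at both times by edgeR's quasi-likelihood test, and 1, Arhgap31, by DESeq2. At an unadjusted p under 0.05 at both times, 4 genes were higher at both, against 8.32 expected of independent lists (one-sided Fisher's exact test, p = 0.969), 3 were lower at both, against 4.13 expected (p = 0.786), and 19 went opposite ways. Arhgap31 and Hspbap1 were the 2 genes with every knock-out library below every wild-type library at both times, and Slc50a1, a sugar transporter, was the 1 gene with every knock-out library above, at 0.45 and 0.41 on the log2 scale. Chance alone would give 0.707 genes in each direction. A further 1 gene was separated at both times in opposite directions. Within single times, 505 genes were separated in either direction at 2 days, against 356.571 expected, and 66 at 14 days, against 99.0476 expected.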

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

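Of the tests in this part, the 1 of total depth in knock-out library 5 at 14 days and the test of lists between times were chosen only after the result was seen. In each group of 4 or 5 libraries, a library was singled out when its gap to the nearest other exceeded the 95% critical value of Dixon's test as a share of the range of the group. This held in 21 of 208 groups, where chance singles out about 1 in 20, or 10.4. The values below are these shares, on log2 CPM for genes.

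Wild-type library 1 at 2 days had the highest total count (0.839, 40.5 against 19.0 M in the next library) and the fewest genes with a count (0.916, 16073 against 18105). It stood apart in the share of satellite-like gene models (0.952), although this share was only 3.26e-04% of its counts. It also stood apart for Itgam (0.881), Rida (0.896), Cyp4f40 (0.868, lowest) and Cd24a (0.936). In wild-type library 3 at 2 days Aim2 (0.912) and Ralgps2 (0.890) were lowest, in library 2 Cdc42 (0.961) and in library 4 Guca2b (0.898). Among knock-out libraries at 2 days, library 3 stood apart in satellite-like models (0.856, at only 2.36e-04% of its counts) and had the lowest Spib (0.870). Knock-out library 1 had the highest Adh6a (0.858), and library 4 the highest Eci2 (0.871). At 14 days wild-type library 3 had the highest mitochondrial share (0.730, 26.3% against 11.6%) and stood apart for Ramp1 (0.714) and Spry2 (0.742), and wild-type library 1 had the lowest Hkdc1 (0.798). Knock-out library 1 at 14 days had the highest enterocyte score (0.730), and knock-out library 5 the highest share of satellite-like models (0.987, 47.0% against 0.658%).

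The genotype effect on 6 lists differed between 2 and 14 days by camera with Benjamini-Hochberg adjustment, with adjusted p of 4.95e-07 for enterocyte, 0.00178 for G2/M, 0.00662 for fatty acid oxidation, 0.0125 for mitochondrially encoded, 0.0365 for dissociation stress and 0.0384 for EGF and MAPK genes. None was called with an estimated correlation, and chance cannot be excluded. Nor can time be told apart from a run or cohort of each table. In 59 of 100 splits of the libraries within each time as many lists were called, with 6 in the real split and up to 18 in another.

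With a preset correlation, enterocyte markers were called higher at 2 days and lower at 14 days in the knock-out libraries, and both calls were lost by camera with Benjamini-Hochberg adjustment when the correlation was estimated (adjusted p = 0.862 and 0.899 with an estimated correlation). Single libraries rich or poor in enterocytes may explain both calls. Without knock-out library 1 (median 0.21 at 2 days) or wild-type library 3 (median -0.10 at 14 days) the calls ended. A different share of stem cells in the sort, if it moved goblet and enterocyte markers alike, cannot be told apart at 2 days. Their difference there lay within the wide spread of the knock-out libraries (two-sided exact permutation p = 0.543). At 14 days goblet moved above enterocyte markers by 0.78 log2 units (two-sided exact permutation p = 0.0159), which argues against such an even change. A sort that took in these cell types unequally would give the same shift and was not excluded. An effect of genotype on differentiation stays open.

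Knock-out library 5 at 14 days had 47.0% of its counts in satellite-like models. Genomic DNA in the library is a candidate explanation, since 1461 olfactory and vomeronasal receptor genes took 201 CPM of unscaled totals in it, against a median of 55.6 and at most 127 in the other 9 libraries of that time. Its total was the lowest of that time, at 11.1 M or 0.827 times the median of those 9. Knock-out libraries 2 and 4, with 11.6 and 11.3 M, had 0.658% and 0.598% of their counts in satellite-like models. These values argue against lower total depth as the source of the 47.0%. No biological explanation was tested.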

How the results depend on the processing

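Of the tests in this part, the robust quasi-likelihood fit, the fit without the 2 libraries that stood apart, the removal of satellite-like and mitochondrial genes, the block by the letter before the number in the column names at 14 days, and the averaged effect and the lists between times were chosen only after the result was seen. No paired analysis was possible because the columns carry no replicate numbers, so the replicate block was not run. DESeq2 and the robust fit gave no list values, the letter block could not be fitted at 2 days, and a minimum count of 50 gave no value for Arhgap31 at 2 days. Leave-outs apart, 1177 values of single genes kept their direction and side of the threshold, 41 gained a call and 1 reversed, and of the lists not called 757 values stayed so, 31 gained a call and 2 reversed. Of 157 values of called lists under alternatives that kept the preset correlation, 145 kept call and direction and 12 lost the call, and in single leave-outs 163 of 208 kept both.

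With an estimated correlation in camera, and with fry, 0 lists were called at 2 days, 14 days and between times. Both tests allow for correlated members. Fry also does not set a list against other genes, so the 2 changes were not separated for it. Without a filter on low counts 7, 2, 98 and 40 genes were called at 2 days, at 14 days, between times and averaged, and 12 lists at 14 days. DESeq2 called 13, 1, 13 and 7 genes in the same order, with 1 gene shared between the times. Upper-quartile factors gave 3 lists at 2 days, and limma voom 11 at 2 days and 13 between times. All 18 libraries in 1 fit gave 2 genes at 2 days. The covariate of Y-linked transcripts gave 2 genes and 3 lists at 2 days, 1 gene between times and 3 averaged. Without the 2 libraries that stood apart 9 lists were called at 2 days and 2 genes averaged. The direction of the list mitochondrially encoded genes, 2d (at 2 days), reversed without these 2 libraries (adjusted p = 0.00144) and with limma voom (adjusted p = 2.52e-05), and the difference of Arhgap31 between times reversed to -0.19 without them. The cause was not tested for any of these apart from the correlation in camera.

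Leaving out single libraries gave 0 to 1 genes at 2 days, 0 to 0 at 14 days, 0 to 1 between times and 1 to 2 averaged, with 0 to 0 shared between times, and 2 to 9 lists at 2 days, 4 to 11 at 14 days and 2 to 8 between times. Signs reversed within the ranges of Cdc42 (-0.22 to 0.058), Habp2 (-0.14 to 0.82) and Defa24 (-0.017 to 0.86) at 2 days, of Gip at 14 days (-0.17 to 1.42), of Arhgap31 between times (-0.18 to 0.74) and of the Paneth median at 2 days (-0.20 to 0.96). The mitochondrially encoded list at 2 days reversed too (adjusted p from 0.00144 to 0.941). Simulated 2-fold changes were recovered in 16.5% at 2 days and 31.3% at 14 days. These shares hold for 200 changed genes and may be lower where few genes change. Depth was not varied apart from spread and number of libraries.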

Other observations

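Of the tests in this part, those of variants linked to the Dlg1 allele, of a single library behind the Arhgap31 call and of the effect averaged over both times were chosen only after the result was seen.

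Arhgap31 was lower in every knock-out library than in any wild-type library at both times. The tables argue against a single library as the source of its averaged call, since the adjusted p stayed between 0.00235 and 0.0179 in the 18 fits without 1 library (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Genes expressed at a similar level had median log2 fold changes of 0.15 at 2 days and 0.0168 at 14 days. TMM scaling sets typical genes near 0 whatever the depth, so these medians cannot decide on lower depth in the knock-out group. At 2 days the mean totals were 22.8 M in both genotypes. At 14 days they were 11.9 M in knock-out and 14.1 M in wild-type libraries. Raw counts of Arhgap31 were then 7 to 35 in knock-out and 118 to 222 in wild-type libraries. These values argue against lower depth as the source of the fall of Arhgap31. Of 132 other genes within 10 Mb of Dlg1, 9.85% had an unadjusted p under 0.05, a share reached by 4.64% of overlapping windows elsewhere. The share lay only narrowly above the 95th percentile, so sequence variants carried along with the Dlg1 allele may contribute but stay open. A response of Arhgap31 to the loss of Dlg1, which the genotypes were made to test, stays open beside this.

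Other splits of the same libraries into groups of the same sizes were fitted in the same way. Where the real split called 0 genes, every split gives as many, so these counts say nothing about chance. At 2 days edgeR's quasi-likelihood test called 0 genes in the real split (640 at an unadjusted p under 0.05, 13 called by DESeq2 and 0 by limma voom) and up to 5 in another of the 35 splits. The split with 5 genes put wild-type libraries 1 and 2 and knock-out libraries 3 and 4 against the rest. These are the libraries with negative means of the sex-linked list, and the splits were not balanced for that list. At 14 days edgeR's test called 0 in the real split (558 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom) and up to 668 in another of the 100 splits. The split with 668 genes put wild-type libraries 1 and 3 and knock-out libraries 1, 3 and 4 against the other 5. This points to a structure of the samples other than genotype. Sex-linked list means, relative to wild type, were 0.954 to 1.67 in the first 5 and wild-type library 4, and -2.32 to -1.50 in the rest. The mitochondrial share was 9.60% to 26.3% in the first 5 and 6.21% to 13.4% in the other 5. What the split followed was not settled. For the difference between times the test called 0 genes in the real split (921 at an unadjusted p under 0.05, 13 by DESeq2 and 0 by limma voom) and up to 2 in another of the 100 splits. Chance could not be excluded for the counts above 0. For the averaged effect 9 of 100 splits gave at least the 1 gene of the real split, with up to 2 in another, and 6 of 100 gave as small an adjusted p. Lists called numbered 5 at 2 days (up to 12 in another split, as many in 27 of 35) and 6 at 14 days (up to 14, as many in 68 of 100).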
